A study of Rattus norvegicus with 12 samples.

How the data were processed

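Total RNA of 12 rat samples had been hybridized singly to 1-colour Agilent arrays: 2 of scraped pleural mesothelial cells (mesothelial control), 2 of tissue around the testis (peri-testicular control), 6 of epithelioid and 2 of sarcomatoid mesothelioma that followed ferric saccharate treatment. Per the labels, RNA was isolated with RNeasy Mini columns and labelled with Cy3 by the One-Color Quick Amp protocol. Per the file headers, Agilent Feature Extraction 9.5.1.1 produced the deposited intensity of each spot, with background subtracted and spatial trends removed within the array and no scaling between arrays. The same deposited files give the mean spot intensity, the median local background intensity and 0 or 1 marks for spots well above background, saturated or uneven, per the file headers. The authors also deposited a table of log2 values for 41088 probes, of which 41012 are in the scanner files. In that deposited log2 table each probe is centred: its median over the 4 control columns was 0 (within 1e-06) for 100% of probes. The medians of its columns were -0.07 and 0.03 (mesothelial), -0.12 and 0.13 (peri-testicular), 0.03, -0.16, -0.03, -0.15, -0.06 and -0.04 (epithelioid) and 0.18 and 0.18 (sarcomatoid). It was used as an alternative input only.

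Each array had 43379 spots for 41012 probes after controls were left out. Signals well above background made up 70.8% to 92.3% of spots, 0 to 5 spots were saturated, and the median coefficient of variation of replicate spots was 3.86% to 9.92%. The 75th percentile of the signal ran from 253.0 to 1242.2 between arrays. Spots marked uneven by the scanner software (48 to 168 per array) were left out, and replicate spots of a probe were averaged. The log2 signal had the array's 75th percentile subtracted. Probes were named through RefSeq accessions (10867 probes), current symbols (5256) or older symbols brought up to date (3579), and 21310 kept the label of the array file. Of 35672 gene labels, 15391 are gene symbols. For a gene with several probes, the probe of highest mean over all arrays stood for it. Probes of a gene passed in opposite directions for 297, 147, 17, 6, 0 and 209 of 4197 genes with several probes, in the order epithelioid and sarcomatoid against mesothelial, the same against peri-testicular, sarcomatoid against epithelioid, and between controls. Genes well above background on at least 2 of 12 arrays were tested (33056), and 2616 dim ones were left out.

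Groups and replicate numbers came from the sample titles. All arrays entered 1 limma 3.58.1 fit (R 4.3.3) with a mean per group and 8 residual degrees of freedom, so groups of 2 borrow the spread of all groups. Contrasts compared each tumour type with each control, the tumour types and the controls. Tests were lmFit, contrasts.fit and eBayes with Benjamini-Hochberg adjustment, and a gene counted as changed at an adjusted p under 0.05. The lists of genes were written before the data were examined: 31 lists, of which 30 with at least 5 measured members were tested by fry and 1, of sex chromosome genes, served to check sex labels. List p-values were adjusted over the 30 lists. The 88 missing values were set to the group mean for list tests only. Camera was run with a preset correlation of 0.01 and with estimated correlations. The comparisons, tests, threshold, other settings and the rule for naming genes were also fixed before the data were examined.

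Genes named in each comparison were the 6 largest rises and 6 largest falls that had adjusted p under 0.05, groups that did not overlap, signal well above background on every array of the higher group, and a gene symbol. From each list came up to 4 measured members of smallest adjusted p and members showing an opposite direction. Cdkn2a, Cdkn2b, Msln, Wt1, Ctgf (now Ccn2), Tfrc, Hmox1, Lcn2, Vim and Cdh1 were always included. Text names a part of these, and a few are not reported here. Kidney genes named outside the rule were chosen after their values were seen.

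Other settings tried were quantile normalization, the median or the 75th percentile of well measured probes for scaling, normexp background correction (offset 50) with either scaling, no filter or a filter on every array, the mean over probes, a robust trended variance prior, arrayWeights, the deposited table, and only the groups compared. Others were a slide block, a replicate block, 4 epithelioid arrays that share the prefix of the original sample number averaged or the prefix as a random block (statmod 1.5.0), each array left out in turn, and both camera tests. Normexp raised the floor on arrays with very bright local background spots (3 to 25 of 45018 on 5 arrays). After seeing the data, normexp without these spots and sets of arrays left out were added. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

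The fit was tested on simulated data with 100 genes changed 4-fold and 100 16-fold per comparison. In the above order it recovered 67, 36, 63, 52, 69 and 38 of the 4-fold and 95, 90, 96, 89, 96 and 89 of the 16-fold changes, and it called 4, 6, 9, 7, 9 and 7 unchanged genes. A list of 20 genes raised by log2 1 was always called, and of 29 unchanged lists 0, or 1 in sarcomatoid against peri-testicular. Error on real, correlated genes stays untested.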

Results

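Rat mesotheliomas differed from scraped pleural mesothelial cells in collagen, protease and growth factor genes, which rose, and in lung, red blood cell and fat cell genes, which fell. The rising lists passed a test of direction but not camera with an estimated correlation between genes, which gave them adjusted p of 0.0790 to 0.411. Values are log2 changes with the standard error of the fit, and n was 2 for the mesothelial control, 2 for the peri-testicular control, 6 for epithelioid and 2 for sarcomatoid tumours. All p-values measure the spread between these samples, because nothing in the sources says that the samples came from separate animals. Both control tissues came from untreated F344 rats of 8 weeks and the tumours from F1 hybrids, so tissue and strain differ together in every comparison with a control. The age of the tumour-bearing rats is not given in the sources used here.

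In epithelioid tumours against the mesothelial control, matrix and receptor genes rose: Col6a1 (4.95 ± 0.35, adjusted p = 1.48e-06), Cdh11 (5.61 ± 0.37, adjusted p = 8.91e-07) and Egfr (3.86 ± 0.28, adjusted p = 1.59e-06). Ptn (7.26 ± 0.32, adjusted p = 8.63e-08), a secreted heparin-binding growth factor, rose with the smallest error of the 6 largest rises. The largest falls were in the lung surfactant genes Sftpc (-12.81 ± 0.42, adjusted p = 2.54e-08) and Sftpa1 (-9.44 ± 0.33, adjusted p = 2.58e-08, measured on 2 of 6 epithelioid arrays). Alas2 (-10.27 ± 0.23, adjusted p = 2.91e-09), which starts haem synthesis in red cell precursors, fell as well. Of 33056 genes tested, 17361 changed, 9137 higher and 8224 lower (52.6% higher), and 14786 of them changed at least 2-fold. Without epithelioid replicate 5 and sarcomatoid replicate 2 the count was 19153, without mesothelial replicate 2 10584, and without the 6 tumour arrays in which kidney genes were high 12028.

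The share of changed genes that were higher fell to 37.8% (of 2009 genes) with normexp background correction and 75th percentile scaling. It was 32.6% (of 20492) with the same setting after very bright local background spots were left out. A slide block gave 11486 changed genes (48.0% higher) and 13 of 30 lists in place of 19. It rests on epithelioid replicates 1 and 2, as slide 3 held no control. Counts within a slide use 1 control array and take the spread from tumour arrays of all slides (5 residual degrees of freedom). Scaling left the median of all genes at 0.12 in this comparison, 0.35 in sarcomatoid against mesothelial, 0.34 in sarcomatoid against peri-testicular and 0.26 between the tumour types. List medians are therefore given relative to the median of all genes, except where both are stated. After a gene or a list that is named in passing, the bracket closes with its adjusted p.

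**Figure D1:**
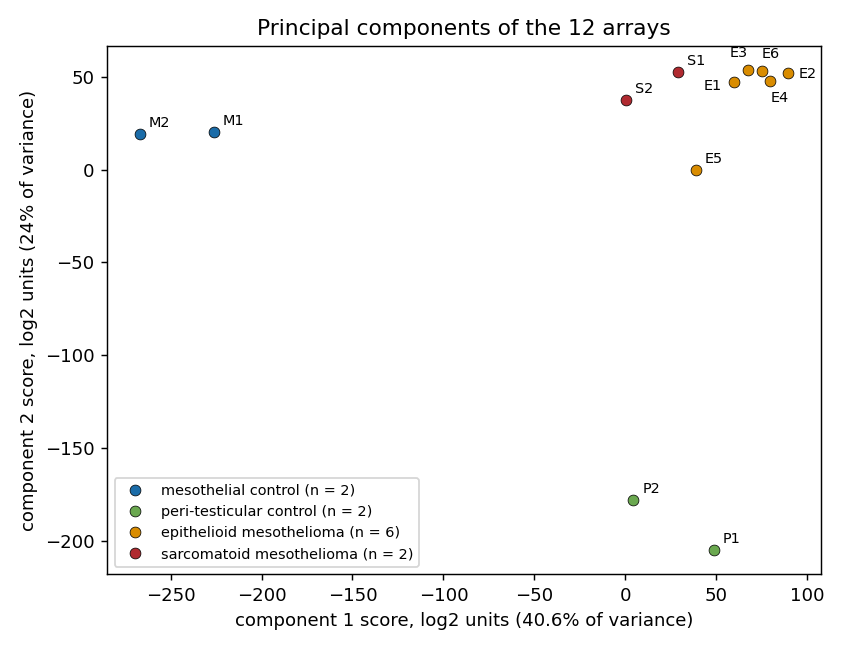
Principal component scores of the 12 arrays over 33056 genes, component 1 (40.6% of variance) across and component 2 (24.0%) up, in log2 units. Mesothelial control arrays lay at -226.2 and -267.0 on component 1, peri-testicular arrays at -205.2 and -178.0 on component 2, and sarcomatoid replicate 2 at 188.6 on component 3 (12.2%, not drawn).

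The other large rises were in genes of varied origin. Slc3a1 (at least 224-fold, adjusted p = 0.00268) encodes a kidney amino acid transporter subunit. It lay at 3.33 to 4.64 in the 6 arrays in which kidney genes were high and at -7.12 to -2.01 in the other 6. Tff3 (7.30 ± 1.77, adjusted p = 0.00521), a mucosal trefoil peptide, followed the same arrays, at 4.26 to 5.50 against -3.70 to 0.19. Cxcl13 (8.40 ± 1.41, adjusted p = 5.46e-04) attracts B cells, Dio3 (8.34 ± 0.95, adjusted p = 3.88e-05, measured on 1 of 2 mesothelial arrays) inactivates thyroid hormone and Rhox5 (7.49 ± 1.19, adjusted p = 3.78e-04) is an X-linked homeobox gene of the reproductive tract. For a gene not well above background in the lower group, the fold is a bound. It sets the mean of the higher group against the lower group with each array raised to its dimmest well measured signal. Among the largest falls were also Alox15b (at least 371-fold, adjusted p = 2.41e-08), a lipoxygenase, and Serpinb10 (-9.04 ± 0.43, adjusted p = 1.21e-07, measured on 3 of 6 epithelioid arrays), a protease inhibitor of bone marrow cells.

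Matrix genes moved as a group. The test used for lists, fry, asks through its PValue whether the genes of a list move on balance one way, and it makes no comparison with other genes. Where fry called a list, the bracket adds camera's adjusted p with an estimated gene correlation, which makes that comparison. Where a slide block ended fry's call, its adjusted p follows. Fibrillar matrix genes rose (21 of 25 rose and 2 fell, 22 and 2 adjusted over the list alone, median 3.37 or 3.25 relative to all genes, 3.21 within slide 1 and 3.28 with a slide block, adjusted p = 5.98e-05, camera 0.326). Bgn 3.37 (4.60e-06), a proteoglycan, Lox 3.62 (4.78e-06), which cross-links collagen, and Col6a2 3.14 (1.12e-05) were among them. Matrix proteases and inhibitors rose (14 of 23 rose and 2 fell, median 2.54, adjusted p = 5.15e-04, camera 0.407). The plasminogen activator gene Plat (6.12 ± 0.42, adjusted p = 1.13e-06, measured on 1 of 2 mesothelial arrays) and Timp1 3.18 (3.99e-06), a metalloprotease inhibitor, rose, whereas Mmp16 -4.13 (1.67e-06) fell. Mesenchymal transition genes rose (10 of 19 rose and 2 fell, 11 and 2 adjusted over the list alone, median 1.66 or 1.55 relative to all genes, 1.78 within slide 1 and 1.84 with a slide block, adjusted p = 5.81e-04, camera 0.506). The transcription factor gene Twist1 5.34 (2.97e-05) and the secreted matrix gene Tgfbi 3.73 (3.92e-06) rose, Vim (1.66 ± 0.22, adjusted p = 1.11e-04) rose, and Snai1 -2.54 (1.40e-05) fell (0.25 with the mean over its probes). In epithelioid replicate 5 the fibrillar matrix score was -0.74, the lowest of the 6 epithelioid arrays.

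Growth signalling genes rose with them. Growth factor receptors and ligands (17 of 28 rose and 3 fell, median 1.84, adjusted p = 1.90e-06, camera 0.0790) included Vegfc 2.47 (1.12e-05), a lymphatic growth factor, Pdgfa 2.26 (3.04e-05) and Fgf2 2.37 (8.01e-05, measured on 1 of 2 mesothelial arrays). YAP-TEAD targets rose (9 of 18 rose and 2 fell, median 0.87, adjusted p = 3.87e-06, camera 0.323), with Ccn2 2.70 (1.27e-04), Myof 2.47 (8.26e-05) and Fjx1 (at least 5.17-fold, adjusted p = 4.35e-06) higher and Axl -2.19 (1.17e-04) lower. Smooth muscle and myofibroblast markers rose (7 of 14 rose and 1 fell, 7 and 2 adjusted over the list alone, median 1.69, adjusted p = 9.60e-06, camera 0.323), among them the contractile genes Tpm2 3.04 (1.63e-06) and Smtn 3.40 (2.88e-06).

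Division and metabolism genes rose as well. Mitosis genes (18 of 28 rose and 3 fell, 19 and 3 adjusted over the list alone, median 1.22, adjusted p = 0.0385, camera 0.671, slide block 0.129) included Tpx2 1.83 (2.11e-04) and Ttk 2.46 (4.01e-04). DNA replication genes (12 of 23 rose and 2 fell, 13 and 2 adjusted over the list alone, median 1.04, adjusted p = 0.00581, camera 0.619, slide block 0.0537) included the primase gene Prim1 2.26 (6.04e-06) and Chaf1b 2.14 (6.87e-05). Hypoxia and glycolysis genes rose (14 of 22 rose and 2 fell, 16 and 3 adjusted over the list alone, median 1.41, adjusted p = 4.04e-04, camera 0.383), with Ankrd37 2.29 (1.40e-05) higher and Vegfa -2.60 (1.11e-04) lower. Mitochondrial respiration genes rose (17 of 29 rose and 1 fell, 19 and 1 adjusted over the list alone, median 0.79, adjusted p = 0.00815, camera 0.63, slide block 0.118), among them Atp5po 1.47 (2.28e-04). NRF2 antioxidant genes rose (10 of 22 rose and 1 fell, median 0.91, adjusted p = 0.00389, camera 0.555, slide block 0.0857), with Gstp1 1.91 (1.11e-04).

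Lists of other cell types fell. Lung epithelium markers fell (13 of 15 fell, median -3.63, adjusted p = 1.69e-09, camera 0.0107), including Sftpb -7.27 (2.54e-08) and Ager -4.88 (1.36e-07). Red blood cell genes fell (9 of 10 fell, median -5.58, adjusted p = 1.26e-08, camera 0.0269), including the anion exchanger gene Slc4a1 -7.07 (1.08e-06), Hbb -8.28 (6.00e-06) and Hbb-b1 -3.88 (3.74e-06). Adipocyte markers fell (18 of 22 fell, median -2.38, adjusted p = 3.58e-07, camera 0.0498), including Ucp1 -7.19 (1.59e-06), the uncoupling gene of brown fat, Adipoq -7.33 (3.04e-06, measured on 5 of 6 epithelioid arrays), Pparg -3.07 (2.05e-06) and Thrsp -4.56 (6.94e-06). These 3 lists were the ones that also passed camera. All 3 were also lower in the peri-testicular than in the mesothelial control.

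Blood and stromal cell lists fell too. Neutrophil and mast cell markers fell (10 of 15 fell, median -1.97, adjusted p = 4.04e-04, camera 0.379), with S100a9 -5.62 (2.11e-07). Lymphocyte markers fell (10 of 18 fell, median -1.70, adjusted p = 0.0110, camera 0.619, slide block 0.0857), with the B cell gene Cd79b -5.83 (1.71e-07). Endothelial markers fell (7 of 18 fell and 1 rose, median -0.66, adjusted p = 8.14e-05, camera 0.326), with Pecam1 -3.12 (5.77e-06) lower and Flt4 (at least 1.97-fold, adjusted p = 0.00148) higher. Flt4 was lower with normexp and the 75th percentile, at -0.19, or -0.32 without bright background spots. Nerve and Schwann cell markers fell (7 of 13 fell and 3 rose, median -1.23, adjusted p = 2.92e-05, camera 0.334), with the myelin gene Mbp -2.97 (8.17e-06). Inflammatory cytokine genes fell (9 of 25 fell and 4 rose, 10 and 4 adjusted over the list alone, median -1.28, adjusted p = 0.00987, camera 0.619, slide block 0.0537), with Cxcl2 -5.36 (3.89e-06) lower and osteopontin, Spp1 6.98 (6.05e-05), higher.

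Mesothelial and iron lists did not pass in this comparison. Of 16 mesothelial markers 9 rose and 2 fell (median 2.74, 0.0843). Epithelioid replicate 2 scored -0.93 and the others 1.40 to 2.21 (control -0.86, -1.05). Pdpn 2.92 (4.14e-06) and Wt1 (3.88 ± 0.77, adjusted p = 0.00161, measured on 1 of 2 mesothelial arrays) rose. Krt8 3.85 (0.00447) and Msln (2.43 ± 0.90, adjusted p = 0.0397) rose, and Calb2 -2.29 (4.17e-05) fell. Of 25 iron genes 11 rose and 9 fell (0.474). Lcn2 (3.17 ± 0.55, adjusted p = 6.77e-04) and the iron importer gene Slc39a14 (at least 3.91-fold, adjusted p = 3.94e-04) rose. Slc25a37 -3.46 (2.46e-06, measured on 4 of 6 epithelioid arrays), a mitochondrial iron importer, and Hpx -2.40 (6.66e-04), the haem carrier, fell. Haem oxygenase, Hmox1 (2.19 ± 0.61, adjusted p = 0.0113), rose and the transferrin receptor gene Tfrc (1.45 ± 1.09, adjusted p = 0.286) did not pass. Cdkn2a (2.03 ± 0.31, adjusted p = 2.82e-04), a cell cycle inhibitor gene, rose, its neighbour Cdkn2b (-0.94 ± 0.31, adjusted p = 0.0263) fell, and Cdh1 (2.42 ± 0.87, adjusted p = 0.0372) rose.

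The remaining lists did not pass: Leydig, Sertoli and epididymis markers (4 rose, 4 fell, 0.0545), WNT pathway targets (5 rose, 7 fell, 0.0564), epithelial junctions (4 rose, 5 fell, 0.201) and germ cell markers (0 rose, 5 fell, 0 and 4 adjusted over the list alone, 0.298). The same held for immediate early and stress genes (8 rose, 7 fell, 0.157), interferon response (7 rose, 5 fell, 6 and 5 adjusted over the list alone, 0.597), macrophage markers (2 rose, 6 fell, 0.349), p53 targets (7 rose, 4 fell, 0.349) and skeletal muscle markers (0 rose, 0 fell, 0.964). Without epithelioid replicate 5 germ cell markers fell (6.81e-06). Single members still moved. The interferon genes Ifit1 -5.57 (8.63e-08) and Rsad2 -6.79 (1.16e-05) fell. The p53 target Eda2r -5.51 (6.53e-08) fell and Gadd45a 3.15 (2.09e-04) rose. Jun 2.83 (8.67e-06) and the heat shock gene Hspa1a 3.32 (1.93e-05) rose. The junction gene regulator Esrp2 -2.82 (1.14e-06) and the WNT target Apcdd1 -3.83 (6.73e-07) fell, and the receptor gene Fzd1 4.03 (5.89e-04) rose. The macrophage genes Msr1 -3.49 (7.78e-05) and Lyz2 -2.75 (1.55e-04) fell. Skeletal muscle genes, such as Myh4 -4.67 (0.0653), did not pass, and their score was 5.19 in epithelioid replicate 5. Median (as such or relative to all genes), mean and test differed in sign for Leydig, Sertoli and epididymis markers, WNT pathway targets, epithelial junctions, immediate early and stress genes, interferon response, macrophage markers and skeletal muscle markers.

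In sarcomatoid tumours against the mesothelial control, the largest rises included matrix and protease genes: Tnn (at least 320-fold, adjusted p = 0.0160), a tenascin, Cthrc1 (7.76 ± 1.52, adjusted p = 0.00247), a secreted collagen repeat protein, and Mmp3 (at least 67.2-fold, adjusted p = 6.22e-04), stromelysin. Col5a1 (6.26 ± 0.61, adjusted p = 3.56e-05) and the membrane protease gene Mmp14 (6.47 ± 0.66, adjusted p = 4.75e-05) rose as well. The largest falls were again Sftpc (-11.52 ± 0.52, adjusted p = 5.03e-07) and Alas2 (-9.74 ± 0.29, adjusted p = 4.86e-08). In all, 12764 genes changed, 7632 higher and 5132 lower (59.8% higher), 11818 of them at least 2-fold. The count was 11955 without epithelioid replicate 5 and sarcomatoid replicate 2, 7712 without mesothelial replicate 2 and 10735 without the 6 kidney-high arrays.

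The share higher was 48.8% (of 1189 genes) with normexp and 75th percentile scaling and 47.6% (of 9378) with that setting and bright local background left out. A slide block gave 12976 genes and 16 lists in place of 17. On slide 2, which held both sarcomatoid arrays and mesothelial replicate 2, 10779 genes passed. Further large rises were Prss35 (at least 211-fold, adjusted p = 0.0101), a serine protease gene, Crabp1 (at least 181-fold, adjusted p = 5.14e-04), a retinoic acid binding protein gene, and Fmr1nb (at least 88-fold, adjusted p = 0.00965), a testis antigen gene. Further falls were the red cell cytoskeleton gene Add2 (-9.26 ± 1.08, adjusted p = 1.05e-04), its transcription factor gene Nfe2 (-8.97 ± 0.81, adjusted p = 2.19e-05, measured on 1 of 2 sarcomatoid arrays) and Cd52 (-8.95 ± 0.43, adjusted p = 6.32e-07), a lymphocyte surface gene.

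Fibrillar matrix genes rose (22 of 25 rose and 1 fell, 23 and 1 adjusted over the list alone, median 4.15 or 3.80 relative to all genes, 4.19 within slide 2 and 4.16 with a slide block, adjusted p = 4.32e-05, camera 0.226), with Col6a1 5.35 (1.06e-05). Proteases and inhibitors rose (12 of 23 rose and 2 fell, 14 and 2 adjusted over the list alone, median 2.54, adjusted p = 8.46e-04, camera 0.411), Mmp3 and Mmp14 among them. Mesenchymal transition genes rose (9 of 19 rose and 2 fell, median 1.58, adjusted p = 8.46e-04, camera 0.449), with Tgfbi 4.73 (1.05e-05) higher and Snai1 -2.21 (3.11e-04) lower (0.49 with the mean over its probes). Growth factor receptors and ligands rose (11 of 28 rose and 3 fell, 14 and 3 adjusted over the list alone, median 1.15, adjusted p = 6.05e-06, camera 0.139), with Egfr 3.34 (4.44e-05) and Vegfc 2.72 (5.91e-05) higher. YAP-TEAD targets rose (6 of 18 rose and 2 fell, 7 and 3 adjusted over the list alone, median 0.46, adjusted p = 2.43e-05, camera 0.411), with Ccn2 3.31 (2.58e-04) higher and Axl -3.05 (1.10e-04) lower. Smooth muscle and myofibroblast markers rose (7 of 14 rose and 1 fell, median 2.04, adjusted p = 8.17e-06, camera 0.205), with Tpm2 3.68 (6.18e-06). Hypoxia and glycolysis genes rose (10 of 22 rose and 2 fell, 11 and 3 adjusted over the list alone, median 0.51, adjusted p = 0.0203, camera 0.639), with Ankrd37 2.14 (1.96e-04) higher and Car9 -3.21 (6.04e-04) lower. DNA replication genes rose (7 of 23 rose and 1 fell, median 0.49, adjusted p = 0.0259, camera 0.639, slide block 0.0595), with Prim1 2.25 (6.45e-05).

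The falling lists were those of other cell types and of inflammation. Lung epithelium markers fell (12 of 15 fell, median -3.40, adjusted p = 1.56e-08, camera 0.00397), with Sftpb -7.08 (5.01e-07). Red blood cell genes fell (9 of 10 fell, median -6.29, adjusted p = 8.76e-08, camera 0.0112), with Slc4a1 -7.06 (1.29e-05). Adipocyte markers fell (17 of 22 fell, median -2.56, adjusted p = 5.04e-06, camera 0.0317), with Ucp1 -7.10 (2.02e-05). Neutrophil and mast cell markers fell (10 of 15 fell, 11 adjusted over the list alone, median -4.63, adjusted p = 1.38e-04, camera 0.205), with S100a9 -5.65 (2.36e-06). Lymphocyte markers fell (11 of 18 fell, 12 adjusted over the list alone, median -2.67, adjusted p = 0.0148, camera 0.411), with Cd79b -5.10 (5.18e-06). Interferon response genes fell (6 of 25 fell and 1 rose, median -0.91, adjusted p = 0.0259, camera 0.487, slide block 0.0998), with Ifit1 -5.62 (1.19e-06) lower. Inflammatory cytokine genes fell (6 of 25 fell and 2 rose, median -1.21, adjusted p = 0.0229, camera 0.435), with Cxcl2 -5.94 (2.26e-05) lower and Spp1 6.17 (0.0010) higher. Endothelial markers fell (4 of 18 fell and 2 rose, median -0.85, adjusted p = 0.0119, camera 0.411), with Pecam1 -2.74 (1.36e-04) lower and Flt4 (at least 3.14-fold, adjusted p = 0.00138) higher (-0.54 with normexp and the 75th percentile). Nerve and Schwann cell markers fell (5 of 13 fell and 1 rose, median -1.41, adjusted p = 8.30e-04, camera 0.322), with Ncam1 3.17 (0.0102) higher.

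Lists that did not pass were Leydig, Sertoli and epididymis markers (1 rose, 4 fell, 1 and 3 adjusted over the list alone, 0.0718), NRF2 antioxidant response (4 rose, 0 fell, 0.266), WNT pathway targets (7 rose, 5 fell, 0.980) and epithelial junctions (0 rose, 4 fell, 0 and 2 adjusted over the list alone, 0.0506). The same held for germ cell markers (0 rose, 3 fell, 0.375), immediate early and stress genes (6 rose, 7 fell, 0.980), iron metabolism (6 rose, 7 fell, 7 and 8 adjusted over the list alone, 0.441) and macrophage markers (0 rose, 5 fell, 0.191). Others below the threshold were mesothelial markers (1 rose, 2 fell, 0.474), mitochondrial respiration (10 rose, 1 fell, 0.0506), mitosis (14 rose, 1 fell, 0.0506), p53 targets (7 rose, 4 fell, 0.324) and skeletal muscle markers (0 rose, 0 fell, 0.725). Within them Pdpn 2.98 (4.01e-05) rose and Calb2 -1.51 (0.00404) fell among mesothelial markers. The mitosis gene Tpx2 2.23 (4.19e-04) and the WNT genes Ccn4 5.55 (0.00434) and Sfrp2 5.57 (0.00561) rose. Cdkn2a 1.21 (0.0273) and Vim 1.93 (3.24e-04) rose and Cdkn2b -1.84 (0.00346) fell. Msln -1.94 (0.183), Wt1 0.81 (0.524, measured on 1 of 2 mesothelial arrays), Cdh1 -1.20 (0.399), Tfrc 0.60 (0.751), Hmox1 1.03 (0.300) and Lcn2 1.73 (0.0640) did not pass. With a slide block p53 targets passed higher (0.0319). Median, mean and test differed in sign for NRF2 antioxidant response, WNT pathway targets, immediate early and stress genes and iron metabolism.

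**Figure D2:**
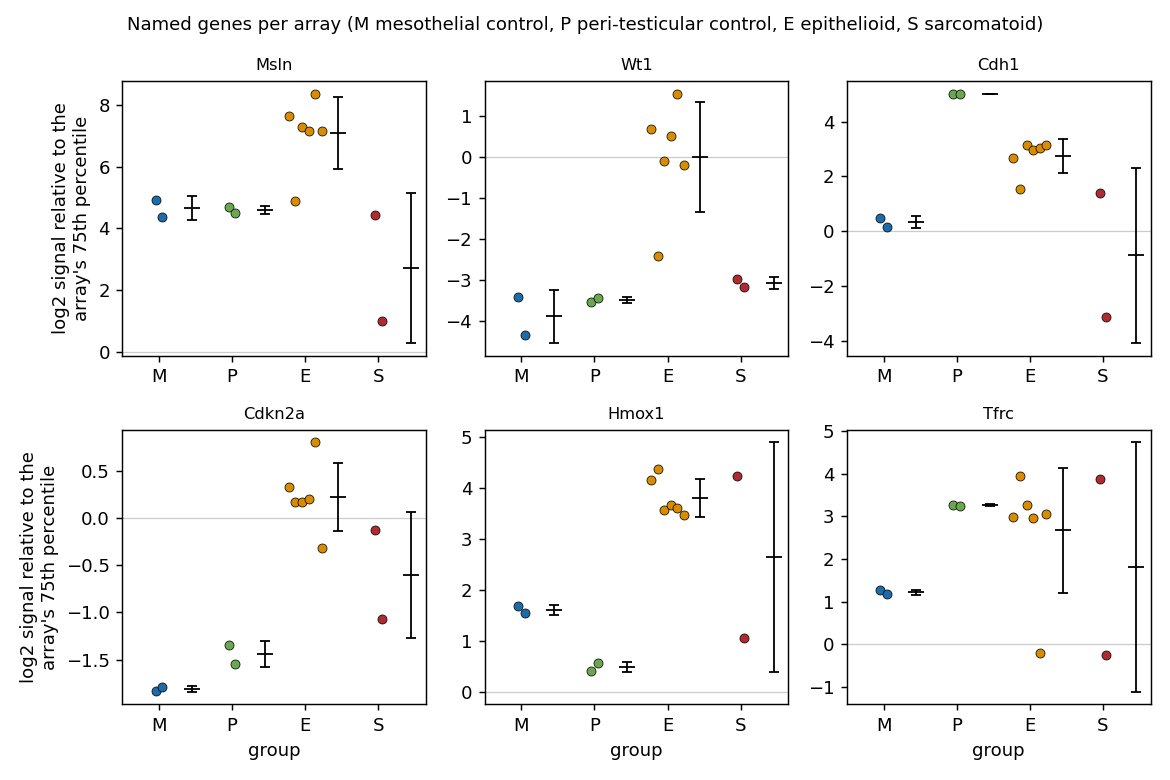
Signal of 6 genes on each array, in log2 relative to the 75th percentile of the array (vertical axis), by group: M mesothelial control (n = 2), P peri-testicular control (n = 2), E epithelioid (n = 6), S sarcomatoid (n = 2). Bars show mean and standard deviation; Msln averaged 4.65 in M, 4.59 in P, 7.08 in E and 2.71 in S.

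In epithelioid tumours against the peri-testicular control, genes of the epididymis fell furthest: Gpx5 (-13.67 ± 0.89, adjusted p = 2.32e-06, measured on 5 of 6 epithelioid arrays), a glutathione peroxidase gene, Lcn6 (-12.37 ± 0.34, adjusted p = 5.22e-09, measured on 3 of 6 epithelioid arrays) and Lcn8 (-12.12 ± 0.59, adjusted p = 2.22e-07, measured on 3 of 6 epithelioid arrays), lipocalin genes, and Rnase9 (-12.30 ± 0.60, adjusted p = 2.22e-07, measured on 3 of 6 epithelioid arrays). Pate7 (-12.03 ± 0.54, adjusted p = 1.20e-07, measured on 5 of 6 epithelioid arrays) and Ly6g5b (-11.82 ± 0.42, adjusted p = 3.18e-08, measured on 2 of 6 epithelioid arrays) fell with them. Fibronectin, Fn1 (5.28 ± 0.24, adjusted p = 1.33e-07), and the tenascin gene Tnc (8.58 ± 1.33, adjusted p = 9.59e-04, measured on 1 of 2 peri-testicular arrays) rose, as did Cxcl13 (9.88 ± 1.41, adjusted p = 5.85e-04). Of 33056 genes 7593 changed, 3561 higher and 4032 lower (46.9% higher), 6465 at least 2-fold. The count was 10360 without epithelioid replicate 5 and sarcomatoid replicate 2, 3026 without peri-testicular replicate 1 and 4193 without the 6 kidney-high arrays. The share higher was 22.6% (of 633 genes) with normexp and 75th percentile scaling. A slide block gave 4113 genes, and within slide 1 it was 2252.

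The other large rises were Cyp4a3 (at least 240-fold, adjusted p = 0.0257), a fatty acid hydroxylase gene, Hao2 (8.16 ± 2.59, adjusted p = 0.0429, measured on 1 of 2 peri-testicular arrays), a hydroxyacid oxidase gene, and Shox2 (at least 72-fold, adjusted p = 0.0010), a homeobox gene. Cyp4a3 and Hao2 are strongly expressed in kidney. They lay at 1.92 to 3.62 and 3.46 to 4.80 in the 6 kidney-high arrays and at -8.35 to -1.61 and -5.81 to -1.20 in the other 6.

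Mesenchymal transition genes rose (11 of 19 rose, 14 adjusted over the list alone, median 1.60, adjusted p = 6.40e-05, camera 0.133), with S100a4 3.89 (3.47e-06). Fibrillar matrix genes rose (15 of 25 rose, 17 adjusted over the list alone, median 1.84 or 1.90 relative to all genes, 2.20 within slide 1 and 2.12 with a slide block, adjusted p = 0.00115, camera 0.214), with Bgn 1.85 (9.43e-04). Proteases and inhibitors rose (12 of 23 rose and 1 fell, 15 and 1 adjusted over the list alone, median 2.03, adjusted p = 0.00112, camera 0.167), with Plat 4.22 (4.69e-05) higher and Mmp7 -2.46 (3.91e-04) lower. Growth factor receptors and ligands rose (8 of 28 rose and 2 fell, 10 and 2 adjusted over the list alone, median 0.90, adjusted p = 1.97e-04, camera 0.133), with Vegfc 2.12 (1.08e-04) higher and Igf1 -2.57 (0.00768) lower. YAP-TEAD targets rose (7 of 18 rose and 4 fell, 12 and 4 adjusted over the list alone, median 0.92, adjusted p = 1.57e-04, camera 0.155), with Ccn1 2.88 (6.09e-04) higher and Wwc1 -3.62 (3.36e-04) and F3 -1.64 (0.00138) lower. Mesothelial markers rose (5 of 16 rose, 8 adjusted over the list alone, median 2.45, adjusted p = 0.0302, camera 0.377, slide block 0.326), with Pdpn 3.19 (6.73e-06). Wt1 3.49 (0.00783), Ccn2 2.19 (0.00150), Vim 2.34 (3.53e-05) and Hmox1 3.31 (0.00289) rose, and Msln 2.49 (0.0688), Cdh1 -2.27 (0.0876) and Tfrc -0.59 (0.747) did not pass. Lcn2 -1.67 (0.0493) fell. Mitosis genes rose (13 of 28, 14 over the list alone, median 1.13, adjusted p = 0.0331, camera 0.377, slide block 0.125), but replicate 5 scored -0.60 (control -0.64, -0.70). The p53 targets rose on balance (6 of 16 rose and 4 fell, 7 and 4 adjusted over the list alone, median 0.55, adjusted p = 0.0121, camera 0.369), with Bbc3 (adjusted p = 6.46e-04) higher and Perp -4.73 (3.20e-04) and Sesn1 -1.81 (0.00136) lower. Cdkn2a 1.66 (0.00299) rose and Cdkn2b 0.90 (0.0615) did not pass.

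Immune and vessel lists rose against this control. Macrophage markers rose (14 of 17 rose, 16 adjusted over the list alone, median 2.85, adjusted p = 0.00609, camera 0.310), with Itgam 4.13 (4.99e-04). Interferon response genes rose (10 of 25 rose, 12 adjusted over the list alone, median 1.12, adjusted p = 0.00375, camera 0.214, slide block 0.111), with Gbp2 3.41 (5.72e-04). Inflammatory cytokine genes rose (7 of 25 rose and 2 fell, 10 and 2 adjusted over the list alone, median 0.75, adjusted p = 0.0118, camera 0.377, slide block 0.117), with Spp1 8.05 (7.44e-05). Neutrophil and mast cell markers rose (6 of 15 rose, 8 adjusted over the list alone, median 1.68, adjusted p = 0.0176, camera 0.369, slide block 0.181), with Hdc 2.54 (0.00465). Endothelial markers rose (7 of 18 rose and 1 fell, 8 and 1 adjusted over the list alone, median 0.72, adjusted p = 1.73e-04, camera 0.133), with Tek 3.48 (4.57e-04, measured on 1 of 2 peri-testicular arrays).

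Epithelial, reproductive and fat lists fell. Leydig, Sertoli and epididymis markers fell (8 of 17 fell and 1 rose, 8 and 2 adjusted over the list alone, median -1.34, adjusted p = 5.88e-06, camera 0.133), with Rnase10 -10.17 (5.22e-09). Epithelial junction genes fell (11 of 19 fell, 14 adjusted over the list alone, median -2.38, adjusted p = 6.40e-05, camera 0.163), with Cldn7 -6.65 (1.33e-07). Germ cell markers fell (8 of 17 fell, 15 adjusted over the list alone, median -2.84, adjusted p = 0.0302, camera 0.377, slide block 0.111), with Smcp -7.72 (0.00408), and their score was 2.84 in epithelioid replicate 5 against 2.67 and 2.70 in the control and -1.51 to -1.16 in the other epithelioid arrays. The call was lost without either control array (0.131, 0.140) or without epithelioid replicate 1, 3, 4 or 6 (0.0515 to 0.0565), and was 9.07e-08 without replicate 5. Adipocyte markers fell (10 of 22 fell and 1 rose, 10 and 2 adjusted over the list alone, median -0.70, adjusted p = 9.80e-05, camera 0.163), with Thrsp -6.14 (2.82e-06). Smooth muscle and myofibroblast markers fell (5 of 14 fell and 1 rose, 6 and 1 adjusted over the list alone, median -0.46, adjusted p = 6.54e-04, camera 0.310), with Cnn1 -3.87 (8.42e-05). Nerve and Schwann cell markers (3 of 13 fell and 2 rose, 3 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.0160, camera 0.757, slide block 0.102) and lung epithelium markers (3 of 15 fell and 1 rose, median 0.08, adjusted p = 0.00204, camera 0.513) were called lower. Gldn -2.87 (8.22e-06) and S100b -3.18 (4.06e-05, measured on 1 of 6 epithelioid arrays) fell and Cnp 1.32 (0.00282) rose among the former. Sftpb -3.65 (3.47e-06) and Hopx -3.44 (1.66e-05) fell and Sftpd 2.64 (0.0441) rose among the latter. The nerve call was lost without peri-testicular replicate 2 (0.152) and turned when signal on every array was required (0.903).

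Lists that did not pass against the peri-testicular control were DNA replication (5 rose, 1 fell, 0.0835), NRF2 antioxidant response (6 rose, 5 fell, 8 and 5 adjusted over the list alone, 0.668), WNT pathway targets (2 rose, 5 fell, 3 and 5 adjusted over the list alone, 0.0562) and hypoxia and glycolysis (6 rose, 4 fell, 8 and 5 adjusted over the list alone, 0.0835). The same held for immediate early and stress genes (7 rose, 6 fell, 8 and 6 adjusted over the list alone, 0.169), iron metabolism (6 rose, 5 fell, 0.273), lymphocyte markers (0 rose, 1 fell, 0.638) and mitochondrial respiration (1 rose, 0 fell, 0 and 0 adjusted over the list alone, 0.673). Others below the threshold were red blood cell genes (1 rose, 0 fell, 0.103) and skeletal muscle markers (11 rose, 0 fell, 15 and 0 adjusted over the list alone, 0.0562). Within them the iron exporter gene Slc40a1 1.73 (0.00269) and Slc39a14 3.34 (0.00182, measured on 1 of 2 peri-testicular arrays) rose and Ltf -5.52 (1.52e-07) and Hfe -1.47 (0.00250) fell. The muscle genes Myl11 6.77 (0.00326) and Myh2 6.62 (0.00392) rose. Median, mean and test differed in sign for iron metabolism, lung epithelium markers and nerve and Schwann cell markers.

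In sarcomatoid tumours against the peri-testicular control, matrix genes rose and epididymis genes fell: Tnn (9.41 ± 2.43, adjusted p = 0.0218, measured on 1 of 2 peri-testicular arrays), Tnc (8.11 ± 1.62, adjusted p = 0.00649, measured on 1 of 2 peri-testicular arrays), Fn1 (5.87 ± 0.29, adjusted p = 6.22e-07) and Mmp3 (7.89 ± 1.15, adjusted p = 0.00110, measured on 1 of 2 peri-testicular arrays) were higher. Gpx5 (at least 21820-fold, adjusted p = 7.14e-06), Rnase9 (at least 7619-fold, adjusted p = 1.17e-06), Lcn6 (-12.41 ± 0.42, adjusted p = 4.50e-08, measured on 1 of 2 sarcomatoid arrays) and Serpina1f (at least 1379-fold, adjusted p = 4.82e-04) were lower. E-cadherin, Cdh1 (-5.88 ± 1.07, adjusted p = 0.00386), fell and Vim (2.60 ± 0.27, adjusted p = 1.21e-04) rose. In all, 6312 genes changed, 3342 higher and 2970 lower (52.9% higher), 6050 at least 2-fold. The count was 6062 without epithelioid replicate 5 and sarcomatoid replicate 2, which leaves 1 sarcomatoid array, 1942 without peri-testicular replicate 1 and 6414 without the 6 kidney-high arrays. The share higher was 38.5% with median scaling, 20.3% (of 449 genes) with normexp and 75th percentile scaling and 40.9% with normexp and quantile scaling. With bright local background left out the last pair were 69.5% (of 9794) and 42.0%. A slide block gave 3710 genes, and within slide 2 it was 1511.

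Fibrillar matrix genes rose (17 of 25 rose, 21 adjusted over the list alone, median 2.68 or 2.33 relative to all genes, 2.70 within slide 2 and 2.78 with a slide block, adjusted p = 3.87e-04, camera 0.237), with Bgn 2.34 (0.00124). Mesenchymal transition genes rose (11 of 19 rose, 14 adjusted over the list alone, median 1.43, adjusted p = 5.03e-05, camera 0.120), with Tgfbi 5.40 (7.14e-06) and S100a4 4.10 (2.04e-05). Proteases and inhibitors rose (12 of 23 rose and 1 fell, 16 and 1 adjusted over the list alone, median 2.30, adjusted p = 8.55e-04, camera 0.258), with Timp2 2.70 (3.70e-04) higher and Mmp7 -3.19 (4.63e-04) lower. Endothelial markers rose (7 of 18 rose, median 0.67, adjusted p = 5.03e-05, camera 0.120), with Plvap 2.55 (0.00145). Growth factor receptors and ligands rose (7 of 28 rose, median 0.40, adjusted p = 3.87e-04, camera 0.40), with Vegfc 2.37 (3.54e-04). YAP-TEAD targets rose (7 of 18 rose and 4 fell, 8 and 4 adjusted over the list alone, median 0.54, adjusted p = 8.15e-04, camera 0.682), with Ccn1 3.88 (5.63e-04) and Ccn2 2.80 (0.00187) higher and Wwc1 -4.11 (9.50e-04) lower. The p53 targets rose on balance (3 of 16 rose and 2 fell, median 0.17, adjusted p = 0.0213, camera 0.817), with Bbc3 1.15 (0.0134) higher and Perp -5.95 (4.65e-04) lower. With median scaling their direction turned (0.834), and the call was lost without sarcomatoid replicate 1 or 2 or peri-testicular replicate 2. Epithelial junction genes fell (14 of 19 fell, 15 and 1 adjusted over the list alone, median -4.59, adjusted p = 5.03e-05, camera 0.120), with Cldn7 -6.44 (1.49e-06). Leydig, Sertoli and epididymis markers fell (7 of 17 fell and 1 rose, 8 and 1 adjusted over the list alone, median -1.54, adjusted p = 2.58e-05, camera 0.120), with Rnase10 -10.87 (4.50e-08). Adipocyte markers fell (8 of 22 fell, 9 adjusted over the list alone, median -0.84, adjusted p = 0.00335, camera 0.223), with Fasn -2.38 (7.88e-05).

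Lists that did not pass here were DNA replication (4 rose, 1 fell, 6 and 2 adjusted over the list alone, 0.237), NRF2 antioxidant response (2 rose, 6 fell, 3 and 6 adjusted over the list alone, 0.166), WNT pathway targets (2 rose, 2 fell, 0.934) and germ cell markers (0 rose, 5 fell, 0 and 10 adjusted over the list alone, 0.0801). The same held for hypoxia and glycolysis (2 rose, 6 fell, 3 and 7 adjusted over the list alone, 0.852), immediate early and stress genes (5 rose, 4 fell, 6 and 4 adjusted over the list alone, 0.934), inflammatory cytokines (5 rose, 0 fell, 7 and 0 adjusted over the list alone, 0.0544) and interferon response (0 rose, 0 fell, 0.506). Others below the threshold were iron metabolism (4 rose, 4 fell, 5 and 5 adjusted over the list alone, 0.0552), lung epithelium markers (2 rose, 3 fell, 3 and 3 adjusted over the list alone, 0.166), lymphocyte markers (1 rose, 1 fell, 0.934) and macrophage markers (8 rose, 0 fell, 9 and 0 adjusted over the list alone, 0.0625). It held for mesothelial markers (1 rose, 2 fell, 0.83), mitochondrial respiration (0 rose, 1 fell, 0 and 0 adjusted over the list alone, 0.492), mitosis (9 rose, 0 fell, 14 and 0 adjusted over the list alone, 0.0552) and nerve and Schwann cell markers (3 rose, 3 fell, 5 and 3 adjusted over the list alone, 0.443). Further ones were neutrophil and mast cell markers (1 rose, 0 fell, 0 and 0 adjusted over the list alone, 0.506), red blood cell genes (2 rose, 0 fell, 0.126), skeletal muscle markers (11 rose, 0 fell, 16 and 0 adjusted over the list alone, 0.0777) and smooth muscle and myofibroblast markers (1 rose, 3 fell, 1 and 4 adjusted over the list alone, 0.0716). The keratin genes Krt8 -5.86 (0.00490) and Krt18 -6.36 (0.0186) fell and Pdpn 3.25 (5.27e-05) rose. Steap3 2.47 (0.00424) rose and Ltf -5.91 (9.76e-07) and Lcn2 -3.12 (0.00956) fell. Cdkn2a 0.84 (0.138), Cdkn2b -0.01 (0.988), Msln -1.88 (0.231), Wt1 0.42 (0.766), Tfrc -1.45 (0.444) and Hmox1 2.16 (0.0663) did not pass. Median, mean and test differed in sign for NRF2 antioxidant response, WNT pathway targets, hypoxia and glycolysis, iron metabolism, lung epithelium markers, nerve and Schwann cell markers and smooth muscle and myofibroblast markers.

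Between the tumour types, limma called 0 of 33056 genes, with 9826 at an unadjusted p under 0.05. The 6 kidney-high arrays, correlated at 0.957 or more, included sarcomatoid replicate 1 (0.976 with epithelioid replicate 2). Without those 6 arrays, which leaves 1 array per tumour type, 2512 genes passed, 909 higher and 1603 lower. Single arrays moved the count: 3727 genes passed without sarcomatoid replicate 1 and 1113 without epithelioid replicate 2. With only the arrays of both types in the fit 1250 passed. Without epithelioid replicate 5 and sarcomatoid replicate 2 the count was 0, and with a slide block it was 0. The types shared no slide, and that fit reaches slide effects only through the controls on slides 1 and 2. The smallest adjusted p was 0.0658, reached by several epithelial and mesothelial genes that were dimmer in sarcomatoid tumours. Mesothelin, Msln (-4.38 ± 0.90, adjusted p = 0.0658), Upk1b (-5.42 ± 1.29, adjusted p = 0.0658), Krt19 (-7.22 ± 1.77, adjusted p = 0.0658, measured on 1 of 2 sarcomatoid arrays) and Krt8 (-3.99 ± 0.91, adjusted p = 0.0658) were among them, as were Cdh1 (-3.62 ± 0.87, adjusted p = 0.0658) and the desmosome gene Dsp (-4.35 ± 0.97, adjusted p = 0.0658).

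The mesothelial marker list had a median of -3.76 (-4.02 relative to all genes) in sarcomatoid against epithelioid. Of its 16 genes 0 passed over all genes, and 14 passed adjusted over the list alone, 13 lower and 1 higher. Its adjusted p was 0.0772 by fry, 1.71e-10 by camera with a preset correlation and 0.277 with an estimated one. Fry called 0 of 30 lists and camera with the preset correlation 12. The mesothelial score ran from 1.40 to 2.21 in epithelioid replicates 1, 3, 4, 5 and 6 and was -0.93 in replicate 2, -0.77 in sarcomatoid replicate 1 and -3.46 in sarcomatoid replicate 2.

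Other genes at that adjusted p, dimmer in sarcomatoid tumours, were the growth factor gene Tgfa -3.64 (0.0658), the mast cell gene Mcpt1 -5.98 (0.0658), Txnrd1 -1.44 (0.0658) and Cdh11 -2.08 (0.0658). Brighter ones were Adipoq 2.44 (0.0658, measured on 5 of 6 epithelioid arrays), Mpo 1.54 (0.0658) and Nos2 2.14 (0.0658). Wt1 -3.07 (0.0663) lay near them. Cdkn2a -0.83 (0.114), Cdkn2b -0.91 (0.0974), Ccn2 0.61 (0.281), Tfrc -0.86 (0.63), Hmox1 -1.16 (0.228), Lcn2 -1.45 (0.117) and Vim 0.26 (0.445) lay further from passing. The other lists had 0 genes that passed over all genes. Medians, genes higher and lower adjusted over the list alone, and adjusted p were NRF2 antioxidant response (-0.98, 0 and 4, 0.117), WNT pathway targets (0.34, 6 and 0, 0.180), adipocyte markers (-0.14, 5 and 0, 0.180), endothelial markers (0.14, 3 and 1, 0.0772), epithelial junctions (-1.03, 2 and 6, 0.213), fibrillar matrix (0.59, 4 and 0, 0.155) and growth factor receptors and ligands (-0.07, 5 and 4, 0.661). In the same form came hypoxia and glycolysis (-0.76, 0 and 3, 0.155), inflammatory cytokines (-0.27, 2 and 4, 0.845), interferon response (-1.29, 0 and 5, 0.0772), mesenchymal transition (0.01, 3 and 2, 0.495), nerve and Schwann cell markers (-0.09, 1 and 0, 0.180), neutrophil and mast cell markers (-1.68, 1 and 7, 0.226) and p53 targets (-0.33, 1 and 0, 0.835). The other 15 lists had 0 genes adjusted over the list alone and adjusted p from 0.0939 to 0.893. Median, mean and test differed in sign for DNA replication, Leydig, Sertoli and epididymis markers, YAP-TEAD targets, adipocyte markers, growth factor receptors and ligands, mitosis, nerve and Schwann cell markers, p53 targets and red blood cell genes.

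**Figure D3:**
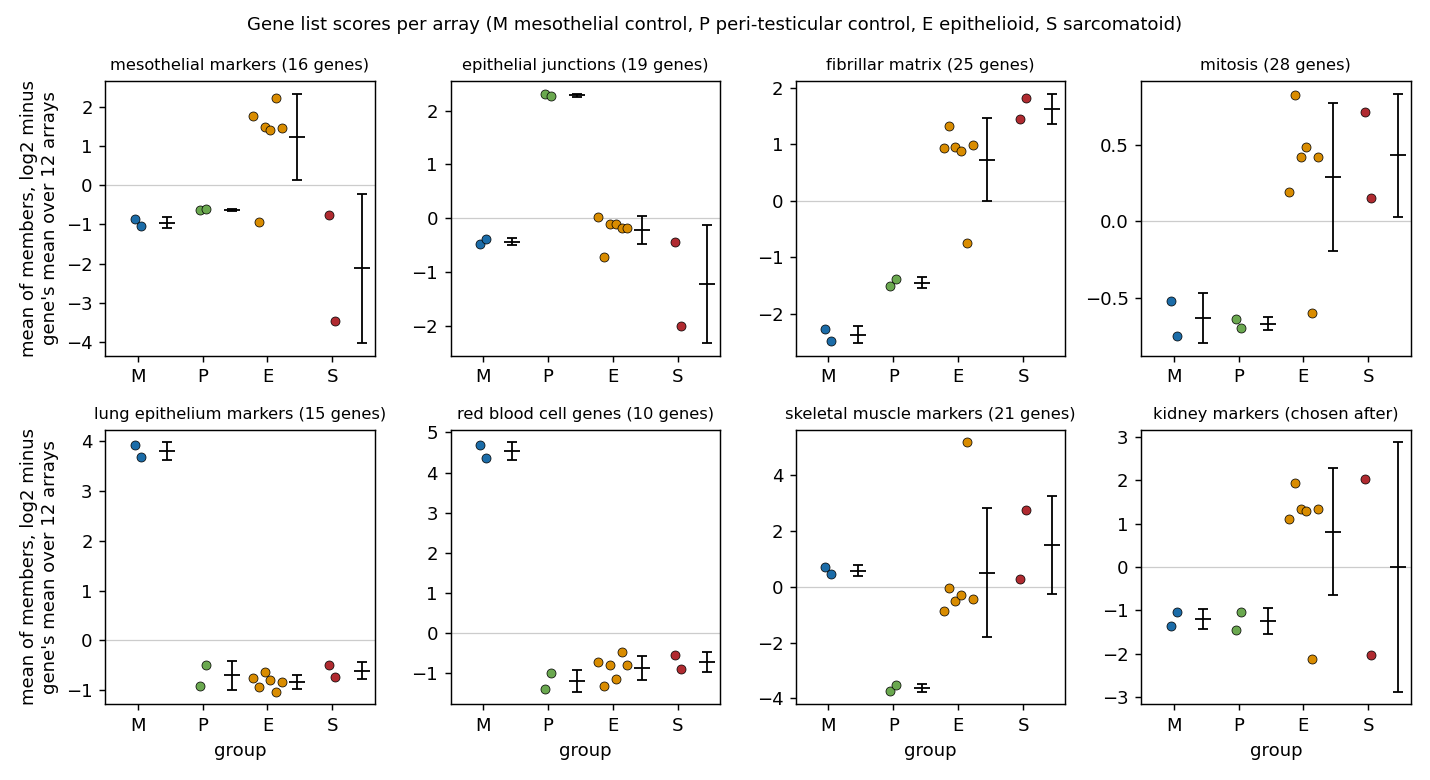
Scores of 7 gene lists fixed in advance and of the kidney markers chosen later, per array, as the mean of members in log2 minus each gene's mean over 12 arrays (vertical axis), by group (M, P and S n = 2, E n = 6). Bars show mean and standard deviation; kidney scores ran from 1.11 to 2.03 in 6 tumour arrays and from -2.12 to -1.03 in the other 6.

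The control tissues also differed from each other. Epididymis genes were higher in the peri-testicular control: Gpx5 (13.03 ± 1.09, adjusted p = 7.03e-06, measured on 1 of 2 mesothelial arrays), Rnase9 (at least 4125-fold, adjusted p = 7.37e-07), Lcn8 (at least 4370-fold, adjusted p = 6.75e-07) and Ly6g5b (at least 1751-fold, adjusted p = 1.48e-07). Lung and blood genes were lower: Sftpc (-13.32 ± 0.52, adjusted p = 1.13e-07), Sftpa1 (-9.66 ± 0.40, adjusted p = 1.21e-07, measured on 1 of 2 peri-testicular arrays) and Alas2 (-10.84 ± 0.29, adjusted p = 1.49e-08). In all, 15656 genes differed, 8248 higher and 7408 lower in the peri-testicular control (52.7% higher), 14664 at least 2-fold. The count was 17785 without epithelioid replicate 5 and sarcomatoid replicate 2, 10354 without peri-testicular replicate 1 and 16676 without the 6 kidney-high arrays. The share higher was 28.8% (of 21563 genes) with normexp and 75th percentile scaling after bright local background was left out. A slide block gave 16481 genes, and within slides 1 and 2, at 1 array against 1 with the spread of tumour arrays, it was 9523 and 9880.

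Lists higher in the peri-testicular control were Leydig, Sertoli and epididymis markers (9 of 17 rose and 4 fell, median 1.86, adjusted p = 2.25e-05, camera 0.520), epithelial junctions (14 of 19 rose and 2 fell, 15 and 2 adjusted over the list alone, median 3.17, adjusted p = 1.85e-04, camera 0.469) and smooth muscle and myofibroblast markers (9 of 14 rose and 1 fell, median 2.24, adjusted p = 3.15e-06, camera 0.139). Adam7 10.58 (3.01e-06), Cldn7 5.33 (2.12e-06), Cdh1 4.68 (0.00424) and Tpm2 4.37 (1.12e-06) were among the rises. Growth factor receptors and ligands (8 of 28 rose and 4 fell, median 0.90, adjusted p = 0.00159, camera 0.470), hypoxia and glycolysis (8 of 22 rose and 3 fell, 8 and 4 adjusted over the list alone, median 0.60, adjusted p = 0.00828, camera 0.673) and YAP-TEAD targets (6 of 18 rose and 4 fell, median -0.04, adjusted p = 0.00335, camera 0.917) rose. The YAP-TEAD call was lost without sarcomatoid replicate 1 or 2 (0.0958 each). Within slide 1 it and the growth factor call were lost (0.119, 0.0786), and both turned with normexp and the 75th percentile without bright spots (0.652, 0.529). Mitochondrial respiration (15 of 29 rose and 2 fell, 16 and 2 adjusted over the list alone, median 0.95, adjusted p = 0.0127, camera 0.676) and NRF2 antioxidant genes (9 of 22 rose and 4 fell, 9 and 5 adjusted over the list alone, median 0.51, adjusted p = 0.0172, camera 0.680) rose.

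Lists lower in the peri-testicular control were lung epithelium markers (13 of 15 fell and 2 rose, median -3.91, adjusted p = 2.61e-08, camera 0.0247) and red blood cell genes (8 of 10 fell, median -5.80, adjusted p = 5.10e-08, camera 0.0247). Neutrophil and mast cell markers (12 of 15 fell, 13 adjusted over the list alone, median -5.05, adjusted p = 6.61e-05, camera 0.328), macrophage markers (13 of 17 fell, 15 adjusted over the list alone, median -2.79, adjusted p = 0.00467, camera 0.658) and lymphocyte markers (7 of 18 fell, median -1.94, adjusted p = 0.0127, camera 0.673) fell, with S100a9 -6.94 (3.66e-07), Lyz2 -4.82 (1.84e-05) and Cd79b -6.47 (5.93e-07). Endothelial markers (13 of 18 fell and 1 rose, 15 and 1 adjusted over the list alone, median -1.55, adjusted p = 3.76e-06, camera 0.0799) and adipocyte markers (11 of 22 fell and 3 rose, median -1.08, adjusted p = 6.15e-04, camera 0.470) fell, with Pecam1 -3.98 (7.25e-06) and Ucp1 -7.22 (9.33e-06). Inflammatory cytokines (13 of 25 fell, median -1.55, adjusted p = 9.27e-04, camera 0.469) and interferon response genes (9 of 25 fell and 1 rose, median -0.70, adjusted p = 0.00828, camera 0.676) fell, with Cxcl2 -5.63 (1.67e-05) and Ifit1 -6.52 (2.09e-07). Mesenchymal transition genes (7 of 19 fell and 3 rose, 8 and 4 adjusted over the list alone, median -0.72, adjusted p = 0.00779, camera 0.676) and nerve and Schwann cell markers (6 of 13 fell and 3 rose, 7 and 3 adjusted over the list alone, median -1.34, adjusted p = 0.00175, camera 0.673) fell. Lists that did not pass between controls were DNA replication (7 rose, 3 fell, 0.182), WNT pathway targets (4 rose, 6 fell, 5 and 6 adjusted over the list alone, 0.897), fibrillar matrix (13 rose, 2 fell, 13 and 3 adjusted over the list alone, 0.113) and germ cell markers (6 rose, 2 fell, 5 and 2 adjusted over the list alone, 0.464). The same held for immediate early and stress genes (5 rose, 9 fell, 0.897), iron metabolism (8 rose, 8 fell, 0.182), matrix proteases and inhibitors (7 rose, 5 fell, 0.897) and mesothelial markers (2 rose, 3 fell, 1 and 2 adjusted over the list alone, 0.787). Others below the threshold were mitosis (2 rose, 4 fell, 0.897), p53 targets (7 rose, 4 fell, 0.0840) and skeletal muscle markers (0 rose, 11 fell, 0.121). Fn1 -4.73 (1.16e-06) fell while Col6a1 3.33 (1.15e-04) rose among matrix genes, and Ltf 6.89 (1.83e-07, measured on 1 of 2 mesothelial arrays) and Lcn2 4.85 (1.93e-04) rose. Msln -0.06 (0.971), Wt1 0.39 (0.761, measured on 1 of 2 mesothelial arrays), Cdkn2a 0.37 (0.452), Ccn2 0.50 (0.382), Tfrc 2.04 (0.233), Hmox1 -1.13 (0.242) and Vim -0.67 (0.0606) did not pass, and Cdkn2b -1.83 (0.00249) fell. With a slide block p53 targets passed lower (0.00148). Median, mean and test differed in sign for YAP-TEAD targets, immediate early and stress genes, iron metabolism, matrix proteases and inhibitors, mesothelial markers, mitosis and p53 targets.

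Both tumour types shared 10879 genes changed the same way against the mesothelial control, 6133 higher and 4746 lower, and 0 changed in opposite ways. Independent lists of the same sizes would share 2110 higher and 1277 lower. Groups simulated without differences shared 0 on average, or 502 at an unadjusted p under 0.05 against 13153 observed. They leave out tissue and strain, and so what the mesothelial control itself adds. Col6a1, Bgn, Lox, Egfr, Ccn2, Twist1 and Cdkn2a were among the shared rises and Sftpc, Alas2, Ucp1 and Cdkn2b among the shared falls. Of all falls in each type, 72.6% (epithelioid) and 83.5% (sarcomatoid) were also lower in the peri-testicular than in the mesothelial control. Part of the excess may come from the shared control tissue, which a separate control array for each type keeps. Without epithelioid replicate 5 and sarcomatoid replicate 2 the shared count was 11313, and without the 6 kidney-high arrays 6709.

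Against both control tissues, epithelioid tumours changed 2776 genes the same way, 1730 higher and 1046 lower, with 984 and 1003 for independent lists, at most 1 simulated and 1579 in opposite ways. At an unadjusted p under 0.05 the simulated mean was 191 and the observed count 4413. Sarcomatoid tumours changed 2039 genes against both, 1542 higher and 497 lower, with 772 and 461 for independent lists, 0 simulated and 893 in opposite ways. At an unadjusted p under 0.05 these were 378 and 3921. Plat, Timp1, Tgfbi, Vim, Pdpn, Vegfc, Ccn2 and Spp1 rose against both controls in epithelioid tumours. Tgfbi, Vim, Pdpn, Vegfc, Ccn2, Tnn, Mmp3 and Spp1 did so in sarcomatoid tumours. The shared tumour arrays count toward each of these overlaps. They were 4349 and 2325 without epithelioid replicate 5 and sarcomatoid replicate 2, and 2077 and 3064 without the 6 kidney-high arrays.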

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

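All tests of explanations below were chosen only after the result was seen, while the test for a lone array standing apart was planned. That test asks, in the group of 6 epithelioid arrays, whether the gap between the highest or lowest array and its neighbour takes up an unusual share of the whole range. Chance alone picks out about 1 in 20 groups, and here 17 of 40 values were picked, 11 in epithelioid replicate 5 and 6 in epithelioid replicate 2. The values share the same 6 arrays and so are not independent.

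Epithelioid replicate 5 stood apart from the other 5 in the mean of these lists, with the share of the range in brackets: germ cell markers (0.92), Leydig, Sertoli and epididymis markers (0.879), lymphocyte markers (0.86), skeletal muscle markers (0.86), WNT pathway targets (0.819), fibrillar matrix (0.791), matrix proteases and inhibitors (0.785), p53 targets (0.722), macrophage markers (0.719) and mesenchymal transition (0.635). It also stood apart in Tfrc (0.763). Its kidney marker value (0.798) is no test, because that list was chosen after this difference was seen. Epithelioid replicate 2 stood apart in neutrophil and mast cell markers (0.886), mesothelial markers (0.742), epithelial junctions (0.73), Cdh1 (0.713), interferon response (0.709) and Msln (0.653).

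Kidney transcripts were high in 6 tumour arrays, epithelioid replicates 1, 2, 3, 4 and 6 and sarcomatoid replicate 1, with Umod at 5.31 to 6.52 against -4.72 to -2.99 in the other 6; Umod, Slc34a1 and Kap were seen first, the list of 33 markers and the 6 arrays were chosen after that, and segments were assigned later still. Carry-over on a slide stays open, since the smallest gap of 2.46 log2 to other arrays follows from how the 6 were chosen. RNA of kidney tissue may have been in the 6 samples, since 12 of the 30 markers not looked at before (40.0%) were higher in all 6 arrays, against 2.8% of all genes. Whether all parts of the kidney took part is open: 0 of 3 markers of the collecting duct or several segments were higher, but Aqp2 was already at 0.92 to 3.09 in the other arrays. Expression by the tumour cells themselves stays open too, as only epithelioid replicate 5 lacked the transcripts among epithelioid arrays (by -3.23 log2), and bounds on carry-over, duct, tumour cells and fat were reworded after the values were seen.

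Lung, blood and fat markers were high in the mesothelial control. For blood, a loss in tumours alone was argued against. This list was also lower in the peri-testicular control, by a median of -5.75 (medians here are not relative to all genes). For lung (-3.86) that control, another tissue, cannot decide. Lung and blood cells in the scraped samples could account for the high values. Medians between epithelioid tumours and the peri-testicular control were 0.02 and 0.58, although fry called the lung list lower there. For fat both explanations stay open, with medians of -1.03 between the controls and -0.76 in epithelioid tumours against the peri-testicular control, where 10 of 22 genes fell. Strain, tissue and perhaps age also differ between controls and tumours and stay open, untested.

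No gene passed between the tumour types. Group sizes too small for any call were argued against, because 1113 genes passed without epithelioid replicate 2. Leaving out sarcomatoid replicate 1 leaves 1 array and cannot decide this. The 0 may come from sarcomatoid replicate 1 standing with the epithelioid arrays or epithelioid replicate 2 with the sarcomatoid ones. Their correlation (0.976) singles out neither, as epithelioid replicates 2 and 3 reached 0.975. Which is out of place stays open, and mixing, mislabelling or an intermediate type was not tested.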

How the results depend on the processing

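The settings without bright local background spots and those without sets of arrays were chosen only after the data were seen, and all other settings were planned. Over all settings, 24162 of 25541 named-gene values kept direction and side of the threshold, 1003 grew weaker, 352 stronger and 24 reversed. Reversed includes genes and lists that did not pass as reported and passed the other way. Of 6120 list values these numbers were 5492, 332, 273 and 23. Of 492 counts of genes, lists or overlaps, 421 stayed within 1.5 times the reported count. Unless stated otherwise the cause was not tested. Comparisons are abbreviated E-M, S-M, E-P, S-P, S-E and P-M, by the initials of epithelioid, sarcomatoid, mesothelial control and peri-testicular control.

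With normexp and the 75th percentile, counts fell to 2009 genes and 12 lists (E-M), 1189 and 10 (S-M), 633 and 5 (E-P), 449 and 5 (S-P) and 1847 and 11 (P-M). Overlaps fell to 986 genes in both tumour types against the mesothelial control, 84 in epithelioid and 73 in sarcomatoid tumours against both controls. In this setting the 10th percentile of corrected signal was 315.7 to 1185 on 5 arrays with bright local background and 61.3 to 91.15 on them once those spots were left out. The setting reversed Flt4 (E-M -0.19, S-M -0.54, P-M -0.03), Fjx1 (S-M -0.07, P-M -0.07), Cenpf (S-M -0.42), Slc39a14 (S-M -0.31), Uhrf1 (S-P -0.11), Cd79b (S-P -0.36), S100a9 (S-P -0.20) and S100b (P-M -0.04). Without those spots S-P rose to 9794 genes and S-E to 1 list. Flt4 (E-M -0.32, P-M -0.31), Fjx1 (P-M -0.34) and S100b (P-M -0.36) reversed, as did growth factor receptors and ligands (P-M, adjusted p = 0.529) and YAP-TEAD targets (P-M, 0.652). Normexp and quantile normalization gave 16 lists in S-P and turned p53 targets to passing lower (E-M 3.42e-04, S-M 0.00141), which passed higher without mesothelial replicate 1 (0.0426, 0.0294) or epithelioid replicate 5 (0.0119, 0.0322). Without bright spots that setting gave 2 genes in S-E and the same turn (E-M 0.00776, S-M 0.0272).

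Median scaling gave 5 lists in S-E and reversed p53 targets (S-P 0.834). The mean over the probes of a gene gave 1 list in S-E and reversed Snai1 (E-M 0.25, S-M 0.49), Uty (E-M -0.31), Apcdd1 (P-M 0.57) and Egfr (P-M -0.22), whose probes differ in direction by the construction of that setting. Requiring signal well above background on every array reversed nerve and Schwann cell markers (E-P 0.903). With arrayWeights E-P rose to 13950 genes and the overlap of epithelioid tumours against both controls to 5363.

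Camera called 15 (E-M), 17 (S-M), 19 (E-P), 12 (S-P), 12 (S-E) and 12 lists (P-M) with a preset correlation of 0.01. With an estimated one it called 3, 3, 0, 0, 0 and 2. With a slide as a block, counts were 11486 with 13 lists (E-M), 4113 with 13 lists (E-P) and 3710 (S-P), and overlaps 1215 in epithelioid and 1321 in sarcomatoid tumours. Of 17361 E-M genes the slide block (epithelioid replicates 1 and 2) kept 11070 and every sign. Within slides, which reuse the same arrays with 1 control array each, 12 of 19 (E-M), 11 of 17 (S-M), 11 of 20 (E-P), 9 of 10 (S-P), and 11 and 12 of 19 (P-M, slides 1 and 2) passed. Epithelioid arrays that share a label prefix, averaged, gave 15317, 12232, 6020, 5902, 0 and 15430 genes. The prefix as a random block gave 15262, 11534, 5560, 4962, 0 and 14622 at a correlation of 0.397.

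With the replicate block counts were 11936 (E-M), 10397 (S-M), 3846 with 10 lists (E-P), 4266 (S-P), 0 (S-E) and 14053 (P-M), the overlap of epithelioid tumours against both controls was 1400, and WNT targets reversed (S-M 0.0284). Deviations of same-numbered samples correlated by 0.487 between controls, whose numbers coincide with slides 1 and 2, and by -0.226 to 0.109 elsewhere. This block groups same-numbered samples, also across slides, and rests on epithelioid replicates 1 and 2.

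With only the arrays of the groups compared, and so fewer residual degrees of freedom, S-M fell to 7804 genes and 11 lists and S-P to 2087 genes, while S-E rose to 1250 genes. The overlaps became 6757 for both tumour types and 765 for sarcomatoid tumours. Without epithelioid replicate 5 and sarcomatoid replicate 2, S-P rose to 18 lists and the epithelioid overlap to 4349, and E-M, E-P and P-M gave 19153, 10360 and 17785 genes. Leydig, Sertoli and epididymis markers (E-M 0.0106), skeletal muscle markers (E-M 0.00521), WNT targets (E-M 0.00340, S-M 8.01e-04, S-P 0.0317), iron metabolism (S-M 0.00541), lymphocyte markers (S-P 0.0143) and NRF2 antioxidant response (S-P 0.0198) reversed. In E-M the Leydig list passed lower without epithelioid replicate 1, 3 or 6 (0.0454, 0.0406, 0.0466) and WNT targets without replicate 1 (0.0334). Adjusted p with 1 array left out reached 0.311 (Leydig list, without epithelioid replicate 5), 0.997 (skeletal muscle, without mesothelial replicate 2), 0.283 (WNT in E-M, without epithelioid replicate 5), 0.993 (WNT in S-M, without epithelioid replicate 6), 0.963 (lymphocyte) and 0.987 (WNT in S-P), both without mesothelial replicate 1. For NRF2 in S-P it ran from 2.53e-04 without sarcomatoid replicate 1 to 0.677 without sarcomatoid replicate 2. Without the 6 kidney-high arrays E-P fell to 4193 genes and 5 lists and S-E rose to 2512 genes and 8 lists, with 1 array per tumour type assumed to vary like the controls. The overlaps were 6709 for both types and 3064 for sarcomatoid tumours. Pygm (E-M 2.00), Actn3 (E-M 2.94) and Tfrc (E-M -1.43, S-M -1.48) reversed, as did epithelial junctions (E-M 0.0232), germ cell markers (E-M 0.0147, E-P 0.423) and skeletal muscle markers (S-E 0.0307). The arrays that remain hold the muscle markers.

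Leaving out 1 array at a time gave 10584 to 18078 genes and 14 to 21 lists (E-M), 7712 to 13805 and 13 to 23 (S-M), 3026 to 9144 and 15 to 23 (E-P), 1942 to 7736 and 9 to 15 (S-P), 0 to 3727 and 0 to 7 (S-E), and 10354 to 16639 and 17 to 23 (P-M). A lone array left in a group is assumed to vary like the other groups. Overlaps ran from 6401 to 11706, 1325 to 3645 and 768 to 2712. The lowest gene counts came without mesothelial replicate 2 (E-M, S-M) or peri-testicular replicate 1 (E-P, S-P, P-M), and the highest, S-E apart, without epithelioid replicate 5. E-P was 3689 without peri-testicular replicate 2, and S-P 3489 without sarcomatoid replicate 2. In S-E, 3727 genes and 6 lists passed without sarcomatoid replicate 1, 1113 and 7 without epithelioid replicate 2, 6 and 5 without epithelioid replicate 5, and 1 without either peri-testicular array. WNT targets (S-M 0.00513) reversed without epithelioid replicate 5 and iron metabolism (S-M 0.0137) without sarcomatoid replicate 2, though without replicate 1 it passed lower (0.0118).

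Signal over background limits the size of falls to near the floor and the 2616 dim genes left untested. Arrays with 70.8% to 92.3% of spots well above background set different floors, so folds given as at least a bound depend on them.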

Other observations

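No test was planned for the values below, and all were looked at after the data were seen. The Y-linked gene Uty was dim in sarcomatoid replicate 2 (-1.15) and in replicate 1 (-1.83), at -1.82 and -2.00 in the mesothelial control and at -0.68 and -0.64 in the peri-testicular control. In epithelioid replicates 1 to 6 it was -1.54, -0.73, -0.87, -0.07, -0.61 and -0.91. The labels of sarcomatoid replicate 2 give both sexes, and this gene separated no array from the others.

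Skeletal muscle markers scored 5.19 in epithelioid replicate 5 and 2.75 in sarcomatoid replicate 2, the tumour arrays without the kidney transcripts. Epithelioid replicates 3 to 6 shared a prefix of the original sample number, and replicates 3, 4 and 6 had fibrillar matrix scores of 0.96, 0.89 and 0.99 against -0.74 in replicate 5. The array columns of the sources include 0 samples outside the groups compared.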
